A study of Homo sapiens with 26 samples.

How the data were processed

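The series measured RNA bound to IGF2BP3, an RNA-binding protein, and RNA levels after its knockdown in PL45, a pancreatic ductal adenocarcinoma line, and Panc1, a pancreatic epithelioid carcinoma line. The 26 samples were grouped from their labels: 3 iCLIP libraries (2 of PL45 and 1 of Panc1), 6 RIP-seq libraries of each line (3 with an IGF2BP3 antibody and 3 with control IgG), 4 RNA-seq libraries of each line (2 with an shRNA against IGF2BP3 and 2 with a control shRNA) and 3 small RNA-seq libraries of Panc1. iCLIP, crosslinking followed by immunoprecipitation and mapping of the crosslinked position, was done on cytosolic detergent extracts, per the labels. RIP-seq, sequencing of RNA co-purified with a protein without crosslinking, used a polysomal lysis buffer, per the labels. The knockdown cells were selected with puromycin at 5 µg/mL for 3 days, and their polyadenylated RNA was taken from cytosolic extracts, per the labels. A directional kit was used for the Panc1 RIP-seq and the RNA-seq libraries, per the labels, and the kit of the PL45 RIP-seq libraries is not given in the sources used here.

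The submitters' processing notes name Bowtie2, TopHat, bedtools and DESeq for the RNA-seq samples, Bowtie2, TopHat and STAR for the iCLIP samples and the build hg19, without versions or roles. The tools behind the RIP p-values and the microRNA values, and the iCLIP peak caller, are not given in the sources used here.

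In the authors' knockdown table each gene has a mean normalized count over all libraries and per group, a fold change deposited as a ratio of the shRNA group over the control group, its log2, a p-value and an adjusted p-value. That deposited table lists genes with an adjusted p of at most 0.1, and its column headers name Panc1 for the PL45 genes too. The number of features behind the adjustment was inferred from the deposited p-values by inverting the Benjamini-Hochberg formula. The deposited RIP tables hold one p-value per gene and replicate, the mean p-value and the authors' target mark. For Panc1 they give p-values of 2 replicates, while the labels list 3. For PL45 the deposited table gives p-values of 3 replicates, each below 0.01, and the mark equals a p below 0.0001 in all 3 for 4650 of 4650 genes. The test behind the RIP p-values and the threshold behind the Panc1 mark are not given in the sources used here. The deposited iCLIP list gives positions, strand, gene symbol and exon class of each site without a score. The microRNA file gives a deposited expression signal per hairpin, in a unit it does not name, for 3 libraries and as their mean. The number of unmapped value columns was 0.

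The design chosen before the data were examined assumed counts per library. The tables hold only the authors' own comparisons, apart from the microRNA values, so its fallback was used: the comparisons are described as deposited at the authors' adjusted p of 0.05, and nothing was refitted. Read depth is unknown for the iCLIP, RIP-seq and RNA-seq libraries, and the knockdown and RIP values carry no spread per library. Positions are given as deposited, on hg19 per the submitters' processing notes, and whether a start counts from 0 or 1 is not stated. The start and end columns of the PL45 RIP table are running numbers and were not used. A RefSeq gene table on GRCh38 served only to find which genes overlap another annotated gene.

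Overlaps between gene sets were tested with Fisher's exact test, two-sided, with the expected overlap given by the product of the set sizes over the background. The background was the 14514 genes of the Panc1 RIP table, except that tests within PL45 RIP used its 4650 genes, the overlap of the RIP targets of both lines used the 4113 genes in both tables, and the overlap of both knockdown lists used the 17800 features inferred as tested in PL45. Medians of sets were compared with permutation tests, two-sided, with 100000 resamples, after a floor of 1e-16 on RIP p-values. Correlations across genes are Spearman's. A standard error of each log2 change was derived from the deposited fold change and p-value, and the difference between lines was tested with the resulting z value. This test is approximate, and in PL45 its standard errors may rest on a control group of 1 library, since the deposited means weight the control by 0.333. Adjusted p-values of these tests follow Benjamini and Hochberg within each family. Shares have 95% Wilson intervals. The 24 gene lists and 10 microRNA lists were fixed before the data were examined, and a list member counted as measured in the knockdown if it was in the Panc1 RIP table. Each list was tested for higher and for lower genes, giving 48 tests per line.

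Genes were named by this rule: the 3 IGF2BP genes; per knockdown, the 10 largest rises and the 10 largest falls past adjusted p 0.05 with a mean level at or above the median of the listed genes; up to 4 members of each list by adjusted p; for RIP, the 15 lowest and 5 highest mean p-values, since no enrichment ratio is given; for iCLIP, the 10 genes with the most sites and up to 15 genes bound in all assays and changed; for microRNAs, the 15 highest means and up to 4 of each list. Some other list members that passed the threshold are named beside the counts, but not all of them.

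Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. On simulated data with a planted effect, the overlap test recovered 100% of planted overlaps and called 4.50% of null ones, the permutation test 97.0% and 6.00%, the Benjamini-Hochberg adjustment 100% with 5.21% false calls among its calls, and the difference test 100% and 5.15%. The difference test was simulated on unselected normal estimates with exact standard errors. Its rates therefore do not carry over to genes already selected for small p-values in both lines.

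The alternatives tried were other adjusted p thresholds, a minimum of 2-fold, a level filter, other backgrounds including matching on gene length or level, targets of the other line, the let-7 list without the targeted gene, sites in last exons alone, means in place of medians, other RIP thresholds, each RIP replicate or microRNA library left out, and other microRNA scalings. The PL45 RIP positions, the library-level fits and any gene without a symbol in the set tests were left out.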

Results

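The data cover IGF2BP3 in PL45 and Panc1 pancreatic cancer cells: which RNAs the protein binds, how RNA levels differ after its knockdown, and which microRNAs Panc1 cells hold. The title of the series asks about cell invasiveness and the RNA-induced silencing complex. Binding was measured by iCLIP in 2 PL45 libraries and 1 Panc1 library, and by RIP-seq in 3 IGF2BP3 and 3 IgG immunoprecipitations per line. Per the labels, knockdown RNA-seq had 2 shRNA and 2 control libraries per line, and small RNA-seq had 3 Panc1 libraries. Depth per library is unknown for iCLIP, RIP-seq and knockdown RNA-seq. The deposited microRNA values summed to 405525, 388565 and 512030 in the 3 libraries. The p-values of the knockdown table measure spread between samples, part of which may be technical. In PL45 the control group may supply no spread, because the deposited means weight it as 1 library. What the RIP p-values measure is not given in the sources used here. Intervals on shares cover counting error only, and genes are not independent replicates.

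The PL45 knockdown asks which RNAs differ when IGF2BP3 is depleted. IGF2BP3 itself fell from a mean normalized count of 3290 to 1231 in the authors' deposited table, a log2 change of -1.42 with adjusted p = 8.78e-04. HMGA2, a chromatin protein of embryonic and tumour cells, fell from 10300 to 3239 in the authors' deposited table (log2 -1.66, adjusted p = 9.51e-06). In all, the authors' deposited table called 36 genes higher and 69 lower, each by at least 2-fold. Beyond HMGA2, the authors' deposited table lists among the largest falls of better expressed genes (those with a mean level at or above the median of the listed genes) OXCT1, an enzyme of ketone body use, which went from 554 to 25.2, the sialic acid receptor SIGLEC6, from 1580 to 113, and the microtubule-associated kinase DCLK1, from 1770 to 246. TMEM47, a membrane protein of cell junctions, had the largest fall among the better expressed genes of the authors' deposited table, with a log2 change of -5.60. CPVL, MKX, DOCK11, MARCKSL1, LRP2 and RCAN2 fell, with log2 changes of -4.32 to -2.64 in the authors' deposited table.

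Among the better expressed genes, the rises in PL45 were led by DNAJC15, a mitochondrial co-chaperone, which went from 2.16 to 281 in the authors' deposited table (log2 7.03), and PDZD2 (log2 5.39). The deubiquitinase USP11 rose from 94.3 to 666, and IGFL1, a secreted factor of the IGF-like family, from 335 to 1275 in the authors' deposited table. FHL1, BAG2, ANTXR1, STMN3, CHST15 and HIST2H2BF rose by log2 changes of 1.84 to 2.56 in the authors' deposited table. Few members of the fixed lists passed the threshold in the authors' deposited table for PL45: HMGA2, IGF2BP3, the duct transcription factor ONECUT2 (1120 to 258, log2 -2.12), lysozyme LYZ of the blood cell list (613 to 187, log2 -1.71), the membrane protease MMP14 (0.720 to 18.0, log2 4.65, adjusted p = 0.00293) and the histone HIST2H2BF. For the interferon list, 0 of 18 measured members were called in PL45. The list with the lowest adjusted p in PL45 was the let-7 targets, with 2 of 21 measured members lower (HMGA2 and IGF2BP3; odds ratio 38.0, adjusted exact p = 0.0796, and 2 when adjusted over the list alone), so no list passed. IGF2BP3 is the gene the shRNA targets, and without it the let-7 list had 1 of 20 measured members lower (adjusted exact p = 0.440). The deposited overall mean weights the PL45 control mean by 0.333 (0.331 to 0.335), as 1 control and 2 shRNA libraries would, although the labels list 2 of each. The corresponding weight in Panc1 was 0.500.

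In Panc1, IGF2BP3 fell from 5140 to 2840 in the authors' deposited table, a log2 change of -0.86 with adjusted p = 0.00868. HMGA2 fell from 9630 to 5320 in the authors' deposited table (log2 -0.86, adjusted p = 0.0129). The authors' deposited table called 1203 features higher and 1055 lower, of which 888 and 768 changed at least 2-fold and 138 and 161 over 10-fold. The largest rises among the better expressed genes of the authors' deposited table were the secretory granule proteoglycan SRGN, from 4.88 to 2390 (log2 8.94), the transcription factor AFF3 (log2 6.91) and the matrix protein tenascin C (TNC), from 245 to 19700 (log2 6.33). The pentraxin PTX3, the caveolar protein SDPR, PRICKLE1, the basal epithelial factor TP63, TNFRSF1B, the protease inhibitor TFPI2 and the matrix protein SPARC rose by log2 changes of 4.68 to 6.13 in the authors' deposited table. The largest falls among the better expressed genes of the authors' deposited table were RASGRF2, a Ras exchange factor, from 942 to 2.28 (log2 -8.69), the gap junction protein GJA1 from 1270 to 16.4 (log2 -6.28) and the surface glycoprotein CD24 from 3270 to 49.1 (log2 -6.06). The desmosomal cadherins DSG2 (2040 to 54.3, log2 -5.23) and DSC2 (log2 -4.83) and E-cadherin, CDH1 (1670 to 54.7, log2 -4.93), fell in the authors' deposited table. PTPN13, KIAA1244, RNF144B and KIAA1147 fell, with log2 changes of -5.43 to -4.25 in the authors' deposited table.

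**Figure D1:**
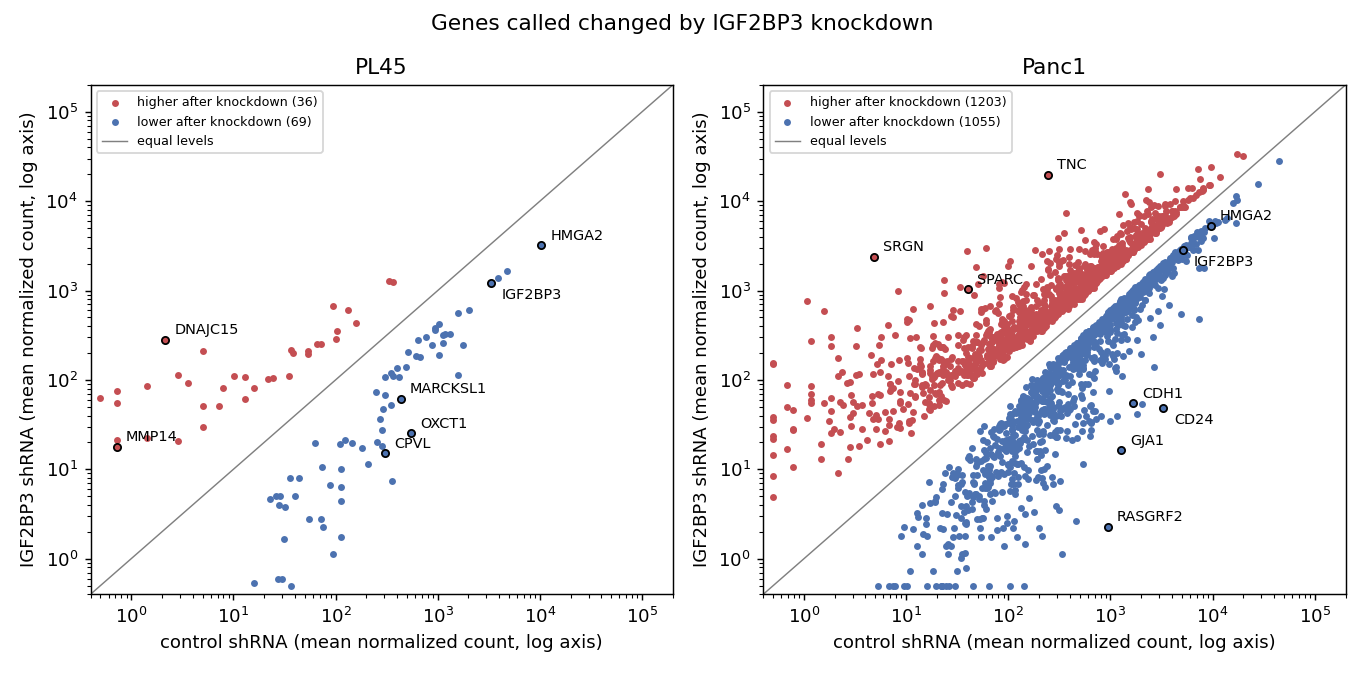
Mean normalized count per gene in control shRNA (horizontal, log axis) and IGF2BP3 shRNA cells (vertical, log axis) for PL45 and Panc1, from the authors' deposited table; red points are genes called higher and blue points genes called lower, the grey line marks equal levels, and counts under 0.5 are drawn at 0.5. PL45 has 36 higher and 69 lower genes and Panc1 has 1203 higher and 1055 lower features.

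Interferon response genes, which cells switch on after sensing virus or interferon, rose together in Panc1: 13 of the 18 measured members were higher in the authors' deposited table and 0 were lower. IFIT1 went from 245 to 1690 (log2 2.78), IFIT2 rose by log2 2.33, IFIT3 by 2.32 and the RNA sensor IFIH1 by 2.24 in the authors' deposited table. Genes of cell adhesion and integrins were higher in 11 of 23 measured members, among them the integrin subunit ITGB4 (182 to 2880, log2 3.98) and ITGA5 (log2 1.79) in the authors' deposited table, while CDH1 and ITGA2 fell. Matrix proteases and their regulators were higher in 6 of 11 measured members, and 8 of all 20 members rose, including the collagenase MMP1 (log2 3.68), matrilysin MMP7 (log2 2.70), the urokinase receptor PLAUR (log2 2.09) and the gelatinase MMP2 (2910 to 8750, log2 1.59) in the authors' deposited table. Epithelial genes were lower in 5 of 12 measured members and 6 of all 16, since EPCAM is not in the background: beside CDH1, the transcription factor ELF3 (log2 -2.68) and the adhesion molecule EPCAM (log2 -2.36) fell in the authors' deposited table, and ESRP1, ESRP2 and OCLN also fell. CLDN4, CLDN7, KRT7 and KRT8 of that same list rose.

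By Fisher's exact test over the 48 tests of the line, these lists passed with odds ratios of 36.7 for interferon genes (1.20 expected, adjusted p = 1.50e-10), 12.9 for adhesion (1.54 expected, adjusted p = 1.75e-06), 16.8 for matrix proteases (0.736 expected, adjusted p = 4.87e-04) and 11.9 for lower epithelial genes (0.682 expected, adjusted p = 0.00398). With the deposited p-values adjusted over the list alone, 14 interferon, 12 adhesion and 8 protease genes were higher and 6 epithelial genes lower. Markers of fibroblasts and stellate cells moved in the same direction as these rising lists: 5 of 9 members rose in the authors' deposited table, with COL3A1 going from 511 to 4720 (log2 3.21), LUM from 3.31 to 381 (log2 6.84), ACTA2 from 18.5 to 249 (log2 3.75) and POSTN from being listed at 0 to 149. DCN was the other one. Only 4 of the markers were in the background, where 2 were higher (adjusted exact p = 0.172, and 5 when adjusted over the list alone), while counting every member as tested gave an adjusted p of 0.00106.

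Targets of the let-7 microRNA family were lower in 5 of 21 measured members in Panc1 (1.19 expected, odds ratio 5.21, adjusted exact p = 0.0534), and 7 of all 25 members fell, 7 also when adjusted over the list alone. They were the cyclin CCND2 (log2 -2.83), the growth factor receptor IGF1R (2900 to 593, log2 -2.29), TGFBR1 (log2 -1.45), LIN28B (log2 -0.99), HMGA2, IGF2BP3 and DICER1 in the authors' deposited table. Counting all members as tested, the let-7 list passed with adjusted exact p = 0.00215. Without IGF2BP3, the targeted gene, 4 of 20 measured members were lower (odds ratio 4.17, adjusted exact p = 0.172, and 0.0114 counting all members as tested). Among silencing complex and microRNA processing genes, the authors' deposited table had DICER1 falling from 4050 to 2250 (log2 -0.85, adjusted p = 0.00392) and TNRC6C from 517 to 222 (log2 -1.22), with 1 of 13 measured members lower and 0 higher. Of mRNAs reported to be bound by IGF2BP proteins, ABCB1, CDK6, HMGA2 and LIN28B fell and CCND3 and IGF2 rose in the authors' deposited table, and the list did not pass (3 of 15 measured lower, adjusted p = 0.218). IGF2, the growth factor that gave the family its name, went from 815 to 2170 in the authors' deposited table (log2 1.42).

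The remaining lists did not pass in Panc1. Higher genes were SPARC, SNAI1 and S100A4 among mesenchymal genes (adjusted exact p = 0.172), where the kinase AXL fell, CDKN1A, FAS and GADD45A among p53 targets (adjusted p = 0.175), and FLNA, MSN, MYH9, MYL9, RHOC and VASP among 36 actin and migration genes (adjusted p = 0.175), where MYH10 fell. FAS, a death receptor, rose by log2 3.87 and FLNA, an actin crosslinker, from 9750 to 24300 in the authors' deposited table. CCNE1, CCNE2 and TOP2A fell among 24 cell cycle genes (adjusted exact p = 0.483). Single members changed among stress response (ASNS lower), glycolysis (HK2 lower), cholesterol synthesis (INSIG1 lower), ribosomal protein (RPS27L higher, 1 of 49) and blood cell genes (CD74 higher). Duct and cancer markers split, with AGR2 (8260 to 1770) and ONECUT2 lower and KRT7 and MUC1 higher in the authors' deposited table. The count was 0 for 43 measured histone genes and for the 2 acinar, 3 endocrine and 2 endothelial markers measured, and 0 mitochondrially encoded genes were in the tables.

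**Figure D2:**
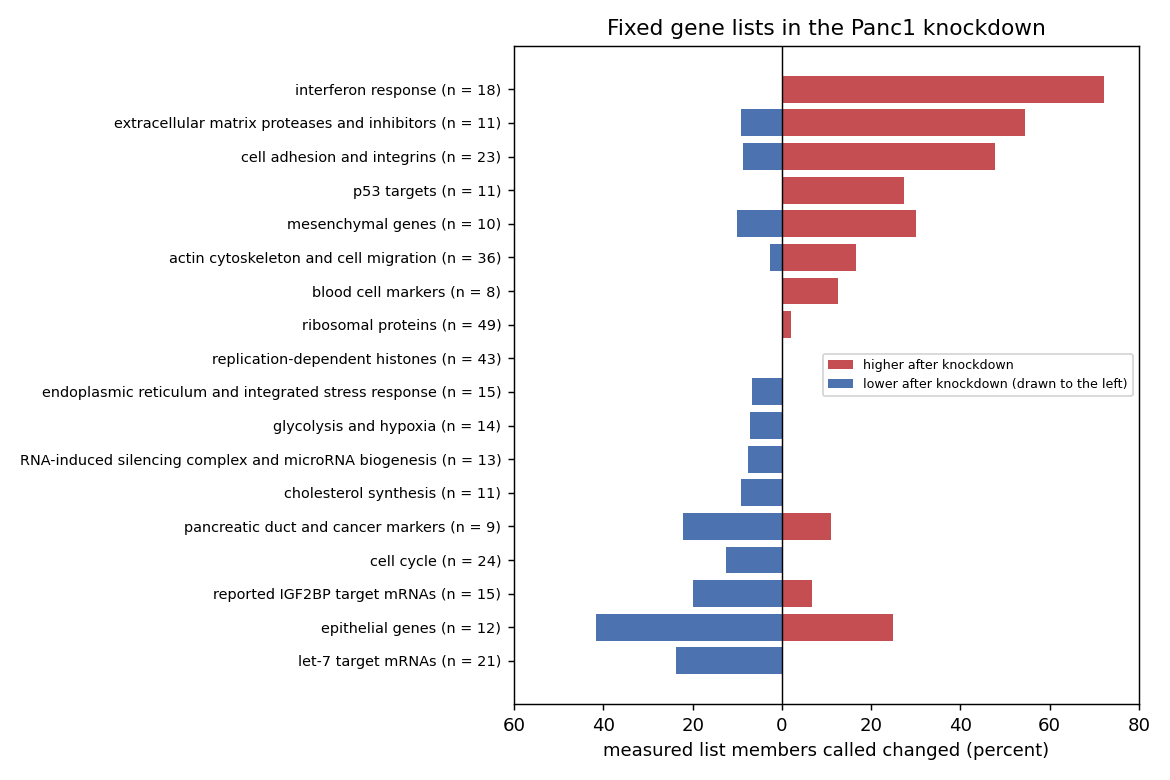
Share of measured members called higher (red, to the right) or lower (blue, to the left) after IGF2BP3 knockdown in Panc1, in percent, with the number measured beside each name, for the 18 fixed lists with at least 8 measured members. Interferon genes have 13 of 18 members higher and 0 lower, while epithelial genes have 5 of 12 lower.

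Comparing the knockdowns of both lines asks which genes respond in each. The authors' deposited table called 38 genes in both lines, where 13.1 were expected by chance (Fisher's exact test, odds ratio 4.02, p = 4.17e-10). HMGA2 and the targeted IGF2BP3 were among the 18 lower in both (4.04 expected, exact p = 5.72e-08), and 8 were higher in both (2.40 expected, p = 0.00213). Another 12 changed in opposite directions, 9 of them lower in PL45 and higher in Panc1. Directions matched in 26 of 38 genes (exact sign test, two-sided, p = 0.0336), but this was not past the threshold at an adjusted p of 0.01 (15 of 22, p = 0.134) or with at least 2-fold changes (21 of 32, p = 0.110). The log2 change of IGF2BP3 in PL45 less that in Panc1 was -0.56, with an approximate standard error of 0.39. By the approximate test of such differences, 37 of the 51 genes tested differed between the lines at an adjusted p of 0.05, and neither IGF2BP3 nor HMGA2 was among them. In all, 53 genes were listed in both lines, and those without a finite log2 change in each line could not be tested. Of the 37, 15 had the same direction in both lines and 22 opposite directions. All 22 tested genes with opposite directions differ by construction, since each was already listed as changed in both lines. The PL45 standard errors behind this test may rest on a single control library. With called genes at or above the median level of the listed genes of their line, 5 were shared (3.22 expected, exact p = 0.254). The background stayed at 17800 features of any level, so this does not test the overlap among better expressed genes.

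RIP-seq in Panc1 asks which RNAs co-purify with IGF2BP3 beyond IgG. The authors marked 1718 of 14514 genes as putative targets, 11.8%. Of the ribosomal protein mRNAs, 46 of 49 measured members were targets in the authors' deposited table, with RPL28, RPL8, RPS23 and RPS24 among the 13 genes whose p is listed at 0 in both replicates. The others listed at 0 were PFN1, an actin-binding protein, FTH1 of iron storage, the poly(A)-binding protein PABPC1, IFIT3, the chromatin protein HMGA1, the tubulins TUBA1B and TUBA1C, LDHA and PLEKHG2. Of the protein family itself, IGF2BP2 had a mean p of 1.28e-15 and IGF2BP3 mRNA, from a gene at 23349827 to 23509995 on chromosome 7 as deposited, a mean p of 2.61e-12, both targets, while IGF2BP1 (mean p = 1.55e-06) was not marked in the authors' deposited table. HMGA2 (mean p = 2.66e-15), CD44 (9.99e-16), a hyaluronan receptor, and CDK6 (1.78e-13) were targets in the authors' deposited table. The highest mean p-values in the authors' deposited table were those of DSCAML1 (0.848), NR1I3 (0.792), KCNT1 (0.761), MPP4 and ELOVL2-AS1 (0.745 each).

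In Panc1, 5 further lists held more Panc1 targets than other genes of the table, beside the ribosomal proteins (5.80 expected, odds ratio 117, adjusted exact p = 4.22e-38, 48 adjusted over the list alone). Actin and migration genes had 20 of 36 (4.26 expected, odds ratio 9.41, adjusted exact p = 3.50e-09, 35 adjusted over the list alone), including PFN1 and ACTN4. Glycolysis and hypoxia genes had 8 of 14 (odds ratio 9.97, adjusted exact p = 4.71e-04, 14 adjusted over the list alone). Previously described IGF2BP targets had 7 of 15 (odds ratio 6.54, adjusted exact p = 0.00523, 13 adjusted over the list alone), CD44, CDK6 and HMGA2 among them. The let-7 targets had 8 of 21 (odds ratio 4.60, adjusted exact p = 0.00892, 18 adjusted over the list alone), HMGA1, HMGA2, IGF2BP2 and IGF2BP3 among them. Adhesion genes had 8 of 23 (odds ratio 3.99, adjusted exact p = 0.0144, 22 adjusted over the list alone). Of the silencing complex and microRNA processing genes, DDX6, DROSHA, TNRC6A and TNRC6B were targets, 4 of 13 (adjusted exact p = 0.140). Epithelial genes had 0 of 12, interferon genes 2 of 18 and histones 1 of 43 (adjusted exact p = 0.140). The mean p fell below 0.05 for 10023 genes (69.1%), so the mark is far stricter than that threshold. Its p followed expression: across 2211 genes the mean p and the control level of the knockdown had a Spearman rho of -0.603.

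In PL45 the authors marked 2223 of 4650 listed genes, each with a p under 0.0001 in all 3 replicates. EHF, an epithelial transcription factor, was listed at 0 in all 3 replicates of the authors' deposited table. The actin regulators ENAH and CAPZA1, the receptor MET and LDHA each had a mean p of 3.17e-14 in the authors' deposited table. HMGA2 (3.18e-14), IGF2BP2 (3.38e-11) and IGF2BP3 (3.81e-10) were targets in the authors' deposited table. Within that table no list held more targets than the other genes after adjustment. Every gene there already had a p below 0.01 in all 3 replicates, so this comparison had little room to show enrichment of a list. Actin and migration genes had 15 of 26 (adjusted exact p = 0.696), duct markers 5 of 5 (adjusted p = 0.299) and silencing complex genes 0 of 8 (3.82 expected, p = 0.00819, adjusted p = 0.196). Against the genes of the Panc1 table as background, the actin list (odds ratio 4.56, adjusted exact p = 7.66e-04), the described IGF2BP targets (5.57, adjusted p = 0.0243) and the let-7 targets (3.92, adjusted p = 0.0363) passed. That wider background counts genes absent from the PL45 table as not targets, so neither background settles the question. Replicate 2 decided many marks in PL45: without it, 3449 genes had a p under 0.0001 in the others.

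The lines shared 1069 targets among the 4113 genes of both tables, where 678 were expected (Fisher's exact test, odds ratio 6.17, p = 2.44e-150). The odds ratio was 3.31 with Panc1 genes called at an adjusted p under 0.01 in both replicates and 21.6 with all genes of the Panc1 table as background. Across the 4113 genes the mean p-values had a Spearman rho of 0.513. Ribosomal protein genes differed between the lines: of the 20 in both tables, 19 were targets in Panc1 and 6 in PL45 by the authors' marks, with 14 marked in Panc1 alone and 1 in PL45 alone (exact McNemar test, two-sided, p = 9.77e-04). This test was chosen after the counts were seen, and the marks rest on different p thresholds in the 2 lines.

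iCLIP asks where IGF2BP3 touches RNA. The deposited list held 259 sites in 244 genes in PL45 and 140 sites in 124 genes in Panc1, with 14 Panc1 sites lacking a gene symbol. Last exons, which hold most 3′ untranslated regions, took 189 of 259 PL45 sites (73.0%, 95% Wilson interval 67.3 to 78.0) and 101 of 140 Panc1 sites (72.1%, 64.2 to 78.9), with no detectable difference between lines (Fisher's exact test, odds ratio 1.04, p = 0.906). Internal exons took 20.5% and 22.1%. The class is that of the deposited exon, which 254 of the 259 PL45 sites and all 140 Panc1 sites touch. The last exons with sites were longer, with medians of 2061 bases in PL45 and 2265 in Panc1, against 128 and 142 for internal exons. Whether last exons held more sites than their length would give was not tested. On chromosome 11 the CD44 site in Panc1 spanned 35253810 to 35253870, inside the last exon that the PL45 list gives whole, 35250675 to 35253949. HMGA2 had a Panc1 site at 66359610 to 66359670 on chromosome 12, and IGF2BP3 mRNA itself had one at 23350230 to 23350290 on the minus strand of chromosome 7, both in last exons. TNRC6B, a silencing complex protein, was bound in both lines, in Panc1 at 40727010 to 40727070 on chromosome 22. In PL45 the CDK6 site was its last exon, 92234234 to 92244600 on chromosome 7. PABPC1 had 4 PL45 sites, all in internal exons. RPS27 had 3 separate sites. DCBLD2 and EEF1A1 had 3 sites each too, but those of DCBLD2 are nested versions of the same exon and 2 of EEF1A1 overlap.

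Sites in the PL45 list are mostly whole exons (248 of 259, median length 1611 bases), and Panc1 sites are multiples of 30-base bins (median 60 bases), so the positions differ in resolution. The lines shared 14 genes: ANXA2, CD44, DEK, EIF4G2, LPP, MTPN, NFAT5, NFIB, NUCKS1, PTMA, SERP1, TMED10, TNRC6B and UHMK1. For MTPN and TMED10 the match rests on the symbol alone, since the deposited sites lie on opposite strands in PL45 and Panc1. Of these, 11 were in the background of RIP-measured genes, where 1.45 were expected (odds ratio 8.77, exact p = 2.15e-07), and 9 had overlapping sites.

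Setting iCLIP beside RIP asks whether both binding assays name the same genes. In Panc1, 59 of 108 iCLIP genes were RIP targets, where 12.8 were expected (Fisher's exact test, odds ratio 9.25, adjusted p = 2.28e-26). In PL45 it was 167 of 212, where 101 were expected (odds ratio 4.30, adjusted exact p = 1.63e-20, and an odds ratio of 21.5 against all genes of the Panc1 table). The median mean p in the authors' deposited table was 2.87e-07 for iCLIP genes and 0.00680 for other genes in Panc1, and 5.12e-09 and 6.02e-05 in PL45. Both differences had a permutation p of 1e-05, the smallest that 100000 resamples can give. Genes bound in iCLIP in PL45 were also Panc1 RIP targets in 147 of 195 cases (23.1 expected, odds ratio 24.9).

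**Figure D3:**
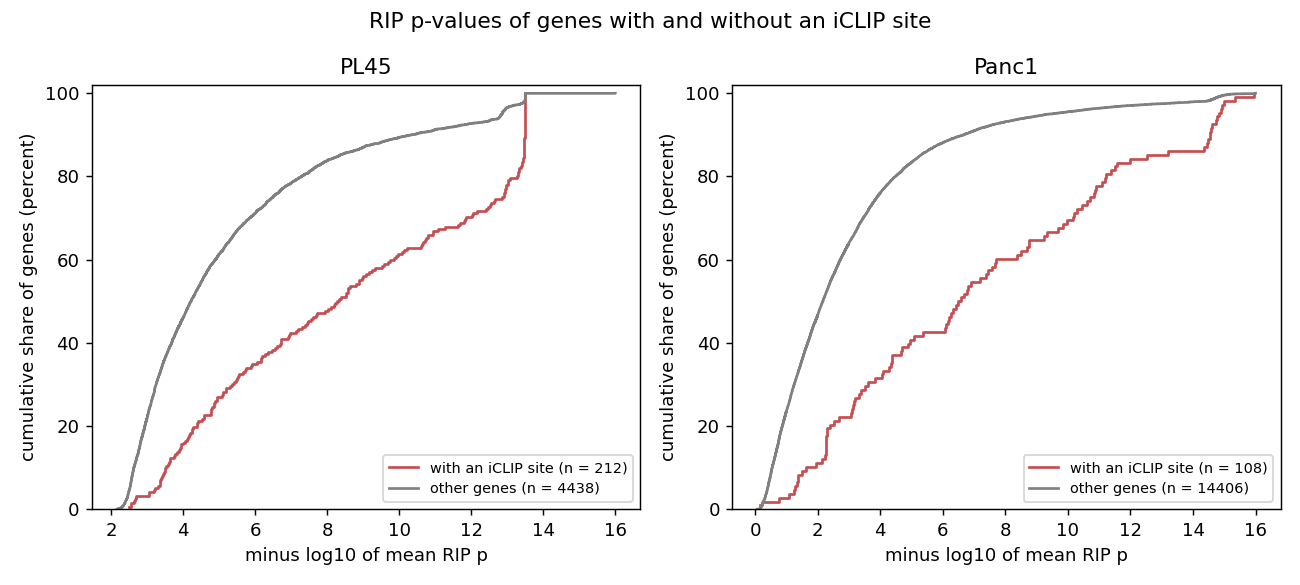
Cumulative share of genes (vertical, percent) by minus log10 of the mean RIP p (horizontal) for genes with an iCLIP site (red) and other genes (grey) in PL45 and Panc1, with p-values under 1e-16 drawn at 1e-16. The red line lies to the right of the grey line, with medians of 5.12e-09 and 6.02e-05 in PL45 and 2.87e-07 and 0.00680 in Panc1.

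Setting binding beside the knockdown asks whether bound RNAs respond to it. Matched by symbol, there were 166 genes with an iCLIP site in either line that were RIP targets in both, of which 10 rose and 11 fell in Panc1 and 2, HMGA2 and IGF2BP3, fell in PL45 in the authors' deposited table. So 21 of the 166 were called in Panc1, a share close to that of all genes of the Panc1 RIP table (1796 of 14514). In PL45, 72 of those 14514 genes were called, and IGF2BP3 is the gene the shRNA targets. Among those of the 166 that rose in the authors' deposited table were the receptor-like protein DCBLD2 (2220 to 10200, log2 2.20), the anti-adhesive sialomucin PODXL (560 to 2000, log2 1.84), the mRNA decay factor ZFP36L1 (log2 1.41), NFIC (log2 0.97), the adhesion molecule ALCAM (log2 0.90) and MSN (log2 0.74). NRIP1 (log2 1.78) and LASP1 (log2 0.95) rose in the authors' deposited table too, but their deposited iCLIP sites lie on the strand opposite to the mRNA, so calling them bound by iCLIP rests on the symbol alone. Those that fell in the authors' deposited table included the atypical cadherin FAT1 (17000 to 5740, log2 -1.57), GPR126 (log2 -0.93), CDK6 (log2 -0.86), the epidermal growth factor receptor EGFR (log2 -0.81) and the hepatocyte growth factor receptor MET (log2 -0.78). The EGFR site, 55240538 to 55240621 on chromosome 7, ends before the exon it is classed by, which starts at 55240675.

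With no minimum fold, neither Panc1 RIP targets nor Panc1 iCLIP genes passed an adjusted p of 0.05 for being called more or less often than other genes. Among 1718 Panc1 RIP targets, 111 were higher in the authors' deposited table (115 expected, odds ratio 0.959, p = 0.719) and 107 lower (97.7 expected, odds ratio 1.12, p = 0.292). With changes of at least 2-fold alone, targets were called less often in both directions, and the odds ratio for lower genes turned to 0.579 (exact p = 4.46e-04). Of 108 Panc1 iCLIP genes, 2 were higher (7.23 expected, odds ratio 0.262, exact p = 0.0494, adjusted p = 0.111) and 8 lower (6.14 expected, odds ratio 1.33, p = 0.402). The 17 iCLIP genes in the authors' deposited table had a median log2 change of -0.85 and the 2723 others one of 0.65, a difference of -1.49 (permutation p = 0.106). The difference in means was -0.67 (permutation p = 0.194). After the median of its level bin was subtracted from each gene's change, the difference in medians was -1.32 (permutation p = 0.0584). All these genes were listed at an adjusted p of at most 0.1, so small changes are largely missing from the medians and means. PL45 RIP targets were lower in the Panc1 knockdown in 164 cases (112 expected, odds ratio 1.63, adjusted exact p = 6.81e-07), but not with changes of at least 2-fold (odds ratio 1.21, p = 0.106). In the PL45 knockdown, 6 RIP targets were higher and 7 lower (4.08 and 5.72 expected), and 0 iCLIP genes of PL45 were called in either direction (0.403 and 0.564 expected, exact p = 1.00 each). Across 2204 genes, the Panc1 RIP p and the log2 change had a Spearman rho of 0.00315 (p = 0.883), and 0.125 (p = 3.23e-05) among genes at or above the median level.

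Small RNA-seq gives the microRNAs that Panc1 cells hold, beside which the let-7 target list and the silencing complex genes can be read. The hairpin with the highest deposited value was mir-21, a microRNA abundant in many tumours, at 55851 ± 6108 (SD, n = 3), or 12.9% ± 0.827 (SD, n = 3) of the summed values. It was followed by mir-30a at 22260 ± 4197 (SD, n = 3), mir-10a at 20647 ± 2111 (SD, n = 3) and mir-29a at 17509 ± 1573 (SD, n = 3). The let-7 and miR-98 family, which represses HMGA2, had 12 hairpins with 11.9% ± 0.869 (SD, n = 3) of the summed values, led by let-7a-2 at 12419 ± 1446 (SD, n = 3) and let-7f-1 at 11914 ± 1360 (SD, n = 3). Next came mir-24-1, let-7b, mir-23a, mir-30c-1, mir-196a-2, mir-16-2, mir-103-2, mir-31 and mir-151, with means from 5539 to 11866. The 15 highest hairpins together made up 49.2% ± 2.69 (SD, n = 3), and the same 15 led under both other scalings and without library x or z, while 14 of them did without library y.

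By family, miR-30 held 9.25% ± 0.524, the miR-17 to miR-92 clusters and paralogues 5.79% ± 0.631, miR-29 5.11% ± 0.137 and miR-34 0.313% ± 0.0556 of the summed values (SD, n = 3). The miR-200 family, which is typical of epithelial cells, held 0.0502% ± 0.00465 (SD, n = 3). MicroRNAs reported high in pancreatic cancer held 33.7% ± 1.03 (SD, n = 3). Those of pancreatic endocrine and acinar cells held 0.723% ± 0.0377, those of blood cells 0.0162% ± 0.00909 and those of liver, muscle, stroma and neurons 2.33% ± 0.233 (SD, n = 3), the last led by mir-9-3 at 2672. No comparison group exists for these libraries. How reads were divided among hairpins that share a microRNA name is not given in the sources used here. For example, let-7a-2 had a mean of 12419 and let-7a-3 one of 307. The rank of a single hairpin therefore cannot be read as that of its gene. The unit is not stated, and library z read a median of 0.47 higher than library x on the log2 scale.

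**Figure D4:**
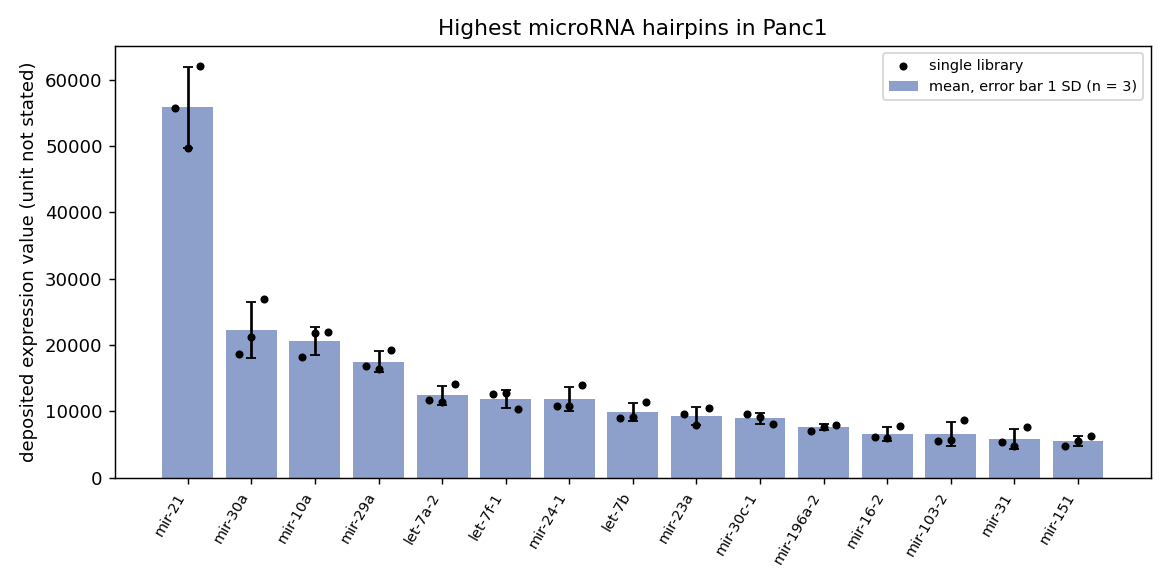
Deposited expression value (vertical, unit not stated) of the 15 microRNA hairpins with the highest mean in Panc1; bars are means, error bars 1 SD and points the 3 libraries. The bar of mir-21 stands at 55851 and the next, mir-30a, at 22260.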

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

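The tests of other cells in the Panc1 knockdown were chosen only after the result was seen. The knockdown changed 12 genes in opposite directions in PL45 and Panc1, past the threshold in each line. The approximate test of the difference is built from the same values, so for these genes it adds nothing to that, and the PL45 values in it rest on a control group that the deposited means weight as 1 library. The complement gene C3 fell by 2.02 in PL45 and rose by 4.53 in Panc1 on the log2 scale in the authors' deposited table, a difference of -6.55 (PL45 minus Panc1, standard error 0.63). SFMBT2, a chromatin protein, rose by 5.90 and fell by 3.99, a difference of 9.89. The differences were 5.93 for L3MBTL4 (3.07 in PL45 and -2.86 in Panc1) and 4.33 for RRAGD (2.56 and -1.78). Those that fell in PL45 and rose in Panc1 in the authors' deposited table were SNAP25 (-4.21 and 2.52, difference -6.73), LOC375295 (-4.16 and 1.54, difference -5.71), RCAN2 (-2.64 and 2.25, difference -4.90), PTPRM (-3.00 and 1.71, difference -4.70), TLE4 (-2.82 and 1.21, difference -4.03), NNMT (-1.35 and 2.56, difference -3.90), SESTD1 (-2.54 and 1.27, difference -3.81) and hCG_1995134 (-1.80 and 0.75, difference -2.55). Several of these changes rest on low mean normalized counts. The PL45 control count was 1.44 for SFMBT2 and 5.04 for RRAGD, and the PL45 shRNA count was 1.67 for SNAP25. In the Panc1 control, C3 had 2.92 and RCAN2 had 2.70. Apart from RCAN2, the 12 genes were chosen for their opposite directions and not by the naming rule.

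In Panc1, 161 genes fell over 10-fold and 137 rose over 10-fold, counting those listed at 0 in one group, while IGF2BP3 itself fell by 0.86 on the log2 scale. A minority of other cells in the knockdown libraries could lower no gene by more than 2-fold, and 768 features fell by at least 2-fold, which argues against it for the genes that fell. For the genes that rose it stays open: 55.6% of the fibroblast and stellate cell markers rose (5 of 9, 95% Wilson interval 26.7 to 81.1), and the levels of the unlisted markers, COL1A1 and COL1A2 among them, are unknown here. Of the 100 genes that fell over 10-fold and are in the RIP table, 0 percent were Panc1 targets (95% Wilson upper bound 3.70%, with 11.8 expected from all genes and 5.87 from genes of like control level). This argues against loss of direct binding for the set only if the RIP cells expressed these genes as the control library did. Their levels in the RIP cells are unknown, and the RIP p follows expression. Whether the control library departs from unmodified Panc1 cells cannot be told apart from a knockdown effect. Presence in the RIP table of unmodified cells did not separate the genes higher in control from those higher in the knockdown (odds ratio 1.17, exact p = 0.553). It could not decide this, because presence there does not track expression: DICER1 and EPCAM, with Panc1 control counts of 4050 and 891, are absent. An indirect biological response to IGF2BP3 loss also stays open, as untested.

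Genes with an iCLIP site were RIP targets far more often than other genes, and a candidate explanation is that both assays favour abundant mRNAs. Control levels exist only for genes listed in the authors' Panc1 knockdown table, and the 47 iCLIP genes among them, pooled over PL45 and Panc1 sites, had a median of 2340 and the others one of 431. Within 10 bins of that level the common odds ratio was 5.00 (95% interval 2.46 to 10.2), against 11.4 without bins, so for these listed genes abundance is argued against as the whole cause and stays open as part of it. Binding of the same mRNAs in both assays remains a hypothesis, and reads shared between related genes were not tested.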

How the results depend on the processing

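Alternatives with other backgrounds, the let-7 list without IGF2BP3, last exon sites, 2-fold changes beside binding, other PL45 RIP thresholds and the median-ratio scaling were chosen only after the result was seen. Of the alternative values, 51 kept their side of the threshold or roughly their size. Of the rest, 10 counts moved, 8 tests newly passed the threshold, 3 tests no longer passed it and 1 reversed. With genes at or above the median level, the calls were 53 in PL45, 1085 in Panc1 and 5 in both (odds ratio 1.61, exact p = 0.254). A cut at the median of the listed genes lowers these calls by construction, and the overlap kept the background of all levels. At adjusted p under 0.01, 22 genes were called in both lines. Calling Panc1 RIP genes by an adjusted p in both replicates gave 6459 genes at 0.01, 8801 at 0.05 and 10014 at 0.1, since these thresholds are looser than the authors' mark. PL45 RIP marks ran from 2232 to 3449 when a replicate was left out, the highest without replicate 2. At p under 0.01 they were 4650, which is every listed gene. Panc1 RIP marks ran from 1928 to 2510. Of 354 iCLIP genes, 14 had sites in both lines. The odds ratio of Panc1 iCLIP genes among higher genes was 0.185 (exact p = 0.0658) with 2-fold changes and 0.183 (p = 0.0632) with last exon sites. Panc1 RIP targets among 2-fold changes had odds ratios of 0.746 for higher genes (p = 0.0300) and, reversed from 1.12, 0.579 for lower genes (p = 4.46e-04), and the Spearman rho rose to 0.125 at or above the median level. Lower genes held PL45 iCLIP genes with an odds ratio of 0.250 (exact p = 0.0260) with 2-fold changes. The cause of these shifts was not tested. The level of mir-21 was 56124 as a share, 57524 by median ratio and 52779 to 58887 with a library left out.

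No paired analysis was possible because the knockdown table carries no values per library, the RIP tables carry p-values without levels, and the microRNA libraries form a single group. For want of such values other normalizations, tools, count filters, pseudocounts, sample sets, replicate blocks and left-out libraries were not run for the knockdown, nor were a 2-fold minimum, normalization, block and level filter for RIP. The iCLIP list carries no score or 3′ untranslated region class, so those thresholds were not run, and matching on level was not run for the gene lists or over all genes of the RIP tables, which carry no levels. Unknown depth limits what an absent call in PL45 can mean.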

Other observations

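The test of overlap with other genes was planned before its result was seen, and the ones of small RNA hosts were chosen only after it was seen. Of the 4650 genes in the PL45 RIP table, 537 are missing from the Panc1 RIP table, EHF, DICER1 and EPCAM among them. A candidate explanation is that genes overlapping another annotated gene were left out before deposit. Of the missing genes matched to the annotation 87.7% overlap another gene, against 61.7% of those present (Fisher's exact test, odds ratio 4.42, p = 6.03e-36). The higher share among the missing genes is what that explanation predicted. Most present genes overlap another gene too, which argues against a filter that left out every overlapping gene of this annotation. Genes holding a small nucleolar RNA or microRNA were 40.1% of the missing and 8.05% of the present ones (odds ratio 7.64, exact p = 1.65e-73). Other filters were not tested. The gap also leaves 49 PL45 and 16 Panc1 iCLIP genes outside every test that uses the Panc1 RIP table.

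The microRNA file marks 15 hairpins with an overlap flag whose meaning is not given, 6 of them from the miR-181 family. Their median value was 322 and that of the other hairpins 49.0, and they held 3.54% ± 0.190 (SD, n = 3) of the summed values. Of 452 hairpins, 407 were above 1 in all 3 libraries. The median coefficient of variation was 31.4%, and 23.2% for the 200 hairpins with a mean of at least 100. Pearson correlations of log2 values between libraries, across hairpins, were 0.980 to 0.982.

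Panc1 RIP targets came from longer genes, with a median of 49416 bases against 21440 for other genes, and the mean p and gene length had a Spearman rho of -0.268 across 14514 genes.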
